A study of Bos taurus with 3 samples.

How the data were processed

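Poly(A)-selected RNA from bovine (Bos taurus) trophoblast stem cells, named bTSCT in the sample titles, was sequenced in 3 libraries. Per the labels' protocols, the cells were grown in DMEM with 15% fetal bovine serum, non-essential amino acids and antibiotics, together with an inhibitor of Rho-associated kinase (Y-27632 at 10 µM), at 37 °C in 5% CO2. RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit. Trophoblast stem cells are the self-renewing cells of the outer layer of the early embryo, which gives rise to the fetal part of the placenta. The series title describes the lines as transformed. The labels place all 3 libraries in 1 group and do not say whether the numbers 1, 2 and 3 stand for separate lines, separate cultures or repeat libraries of a single culture. The spread between libraries given here may therefore be technical.

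The authors deposited raw read counts per gene, as whole numbers, in a single table with 1 column per library and 36075 Ensembl gene identifiers. The column names equal the sample titles, and 0 columns belonged to no sample. FastQC and STAR are named in the submitters' processing notes without a version or role. The read counter, genome build, annotation release and strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes may share or lose reads in ways that could not be checked. The table gives no gene symbols, lengths or positions. The reference table used for names holds 37063 RefSeq genes of the ARS-UCD2.0 assembly, and 0 of the 36075 identifiers could be matched to it. No gene is therefore named, no coordinates are printed, and no gene name was inferred from an identifier or from the order of rows. The 26 marker gene lists fixed before the data were examined, among them trophoblast, epithelial, pluripotency, hypoblast, mesenchyme, blood and interferon-response lists, gave no result for the same reason. The shares of mitochondrial, ribosomal protein and histone genes were likewise not computed. The rule for named genes took genes with symbols and so named none. The 4 identifiers printed are the 2 with the largest range among genes whose most distant library was higher than the others and the 2 with the largest range among those whose most distant library was lower. They were chosen after their values were seen.

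CPM values (counts scaled to a common library total of 1000000) were computed from the deposited counts with edgeR 4.0.16 in R 4.3.3, using trimmed mean of M-values (TMM) library sizes, and values on the log2 scale are log2(CPM + 1). Fold changes on that scale understate the differences of genes at low levels. A gene was called detected at 1 CPM or more. Agreement between libraries was measured by Pearson's r and Spearman's rho across all 36075 genes, which are not independent replicates, and by the common biological coefficient of variation from edgeR's dispersion estimate under an intercept-only model over the 12982 genes at 1 CPM or more in at least 1 library. A chi-square of counts between each pair of libraries, over genes with 20 or more counts in the pair, was used to look for a library deposited more than once. Genes that differed between libraries were counted among those with a mean of 5 CPM or more in 2 ways. The first was a range between the highest and lowest library of 1 or more on the log2 scale. The second was a chi-square test of the 3 counts against the expectation from TMM library sizes, with Benjamini-Hochberg adjustment at 0.05, which tests these libraries against counting noise and not a biological condition. With 1 group there was no contrast to test between conditions, and no library was treated as a condition.

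The procedures were tested on simulated counts drawn with the real means and library sizes. In 1 library 200 genes were changed, 100 by 1.5-fold and 100 by 3-fold. The changed genes were drawn from those with a mean of 10 CPM or more, so recovery from 5 to 10 CPM was not tested. With Poisson noise and 10156 genes run, the chi-square test recovered 100% of the genes at both fold sizes and called 12 unchanged genes. With negative binomial noise at the fitted dispersion and 10137 genes run, the range rule recovered 3% of genes changed 1.5-fold and 100% of those changed 3-fold, with 6 unchanged genes called. In the same counts the negative binomial deviance test recovered 6% and 100%, with 2 unchanged genes called. The chi-square test recovered 97% and 100% there but also called 7962 unchanged genes, so its calls do not separate genes that differ from genes with the spread shared by all. In simulated libraries without changed genes the estimated biological coefficient of variation was 12.1%, for libraries drawn with the dispersions fitted to the real ones.

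The total count was 32984831, 39545032 and 34695036 in replicates 1, 2 and 3. At these depths the 3 counts that a count of 0 allows correspond to 0.0938, 0.0747 and 0.0851 CPM on TMM library sizes. Shares of counts of a single library are given with Wilson 95% confidence intervals. These intervals and limits cover counting error only, since reads amplified by PCR and counted without molecular identifiers are not independent molecules. For the tests on row order, the log2 ratio of each pair of libraries was centred on its median and limited to 1 in either direction. Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors and plain totals in place of TMM, other pseudocounts, level filters and thresholds, a negative binomial deviance test at edgeR's trended dispersion, and leaving out each library in turn. Leaving out a run of neighbouring abundant rows and thinning each library to 10000000 counts were added after the data were seen.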

Results

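The transcriptome of the bovine trophoblast stem cells named bTSCT was profiled by poly(A) RNA sequencing in 3 libraries of a single group. The series addresses the characterization of transformed trophoblast stem cell lines. No other cell type, treatment or edited line was analysed here, so the comparisons made were between levels within a library and between the libraries themselves. Library totals ranged from 32984831 to 39545032 counts. Genes were listed by Ensembl identifier without symbols, and expression is therefore described by number, level and spread of genes and not by gene name.

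Of 36075 genes, 12254 (34.0%) reached 1 CPM in all 3 libraries, and 12982 did so in at least 1 library. A further 14199 genes (39.4%) had no count in any library. For each of these the limit that a count of 0 allows was between 0.0747 and 0.0938 CPM per library, depending on its TMM library size. The number of genes at 1 CPM or more was 12614 ± 76.8 (SD, n = 3), and the number with any count was 19505 ± 267 (SD, n = 3). The deepest library, replicate 2 with 39545032 counts, had the fewest genes at 1 CPM or more, at 12532.

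Most expressed genes lay between 10 and 100 CPM, while most counts came from genes above that level. There were 3736 ± 75.2 genes from 1 to 10 CPM, 6862 ± 25.3 from 10 to 100 CPM, 1921 ± 18 from 100 to 1000 CPM and 95.7 ± 7.09 at 1000 CPM or more (SD, n = 3 for each). The genes from 10 to 100 CPM held 27.0% ± 0.807 of all counts. Those from 100 to 1000 CPM held 44.5% ± 0.735, and the small group at 1000 CPM or more held 26.8% ± 1.54 (SD, n = 3 for each). Genes under 1 CPM together held 0.155% ± 0.0068 of the counts (SD, n = 3).

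**Figure D1:**
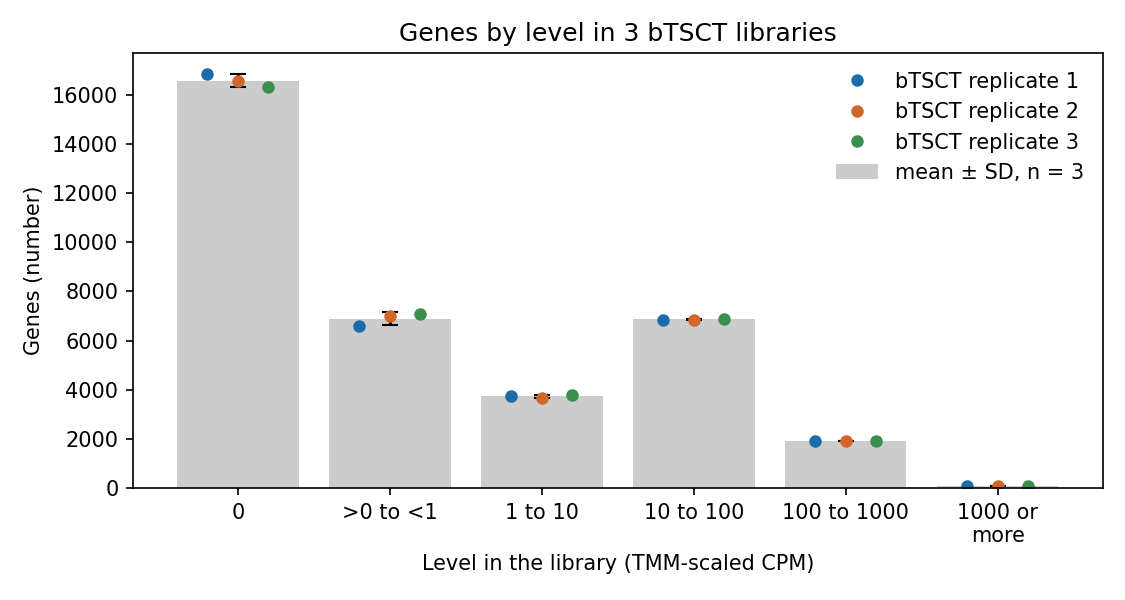
Number of genes (y axis) in each band of TMM-scaled CPM (x axis) in the 3 bTSCT libraries. Grey bars are means, whiskers are SD (n = 3) and points are single libraries. The band from 10 to 100 CPM held 6862 genes on average and the band at 1000 CPM or more held 95.7.

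The most abundant transcripts were largely shared between libraries, but their share of the counts was not constant. The 10 most abundant genes of each library took 10.5% ± 0.868 of its counts and the 100 most abundant took 27.3% ± 1.28 (SD, n = 3). Of the top 10, 8 genes were common to all 3 libraries, and of the top 100, 88 were. The same gene ranked first in every library. It took 2.90% of counts in replicate 1 (Wilson 95% confidence interval 2.89 to 2.90%), 1.88% in replicate 2 (1.88 to 1.89%) and 3.77% in replicate 3 (3.76 to 3.78%). The spread between libraries was therefore far wider than the counting error of any one of them.

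This gene lay in a run of 37 consecutive rows of the table whose identifier numbers lie within 100 of its own, and other members of the run were also abundant. The run was delimited after the values were seen. It held 2 of the 10 and 9 of the 100 genes with the highest mean CPM. Its share of all counts was 5.78% in replicate 1 (Wilson 95% confidence interval 5.77 to 5.79%), 3.73% in replicate 2 (3.73 to 3.74%) and 7.26% in replicate 3 (7.25 to 7.27%), with a mean of 5.59% ± 1.77 (SD, n = 3). Of the 33 members with a mean of 1 CPM or more, 26 were highest in replicate 3 and 29 were lowest in replicate 2. The order replicate 3, then 1, then 2 was found in 24 of these members. Among genes outside the run with a mean of 5 CPM or more, 15.6% had that order. Members of the run may vary together, so these counts are not separate pieces of evidence. The median ratio of replicate 3 to replicate 2 over the 33 members was 1.99, with extremes of 0.909 and 4.26. With the run left out of both the ranking and the total, the top 10 of the remaining genes took 8.57% ± 0.321 of the remaining counts. The top 100 of them took 24.2% ± 1.02 (SD, n = 3).

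Levels agreed closely between libraries. Across genes, Pearson's r of log2(CPM + 1) was 0.998 for replicates 1 and 2, 0.998 for replicates 1 and 3 and 0.997 for replicates 2 and 3. Spearman's rho was 0.958, 0.956 and 0.957 for the same pairs. Over genes at 1 CPM or more in at least 1 library, mean rho was 0.993 and mean r was 0.993. The common biological coefficient of variation was 12.3%. By pairs it was 11.7% for replicates 1 and 2, 11.5% for replicates 1 and 3 and 13.4% for replicates 2 and 3. The typical gene did not follow this order: among genes with a mean of 5 CPM or more, the median absolute difference in log2(CPM + 1) was 0.142 for replicates 1 and 2, 0.140 for replicates 1 and 3 and smallest, at 0.135, for replicates 2 and 3.

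The libraries nevertheless differed by more than sampling of reads. The chi-square of counts divided by its degrees of freedom, which is near 1 for repeated sampling of a single library, was 33.8 for replicates 1 and 2, 33.5 for replicates 1 and 3 and 54.9 for replicates 2 and 3. No pair thus looked like a single library deposited more than once, and all 3 were counted separately. The median SD of log2(CPM + 1) between libraries was 0.17 for genes from 1 to 10 CPM, 0.12 from 10 to 100 CPM, 0.11 from 100 to 1000 CPM and 0.14 at 1000 CPM or more. Simulated Poisson counts of the same depth gave 0.080, 0.033, 0.014 and 0.0040 in these bands. In each band the spread between libraries thus exceeded counting error, by the widest margin in the most abundant genes.

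**Figure D2:**
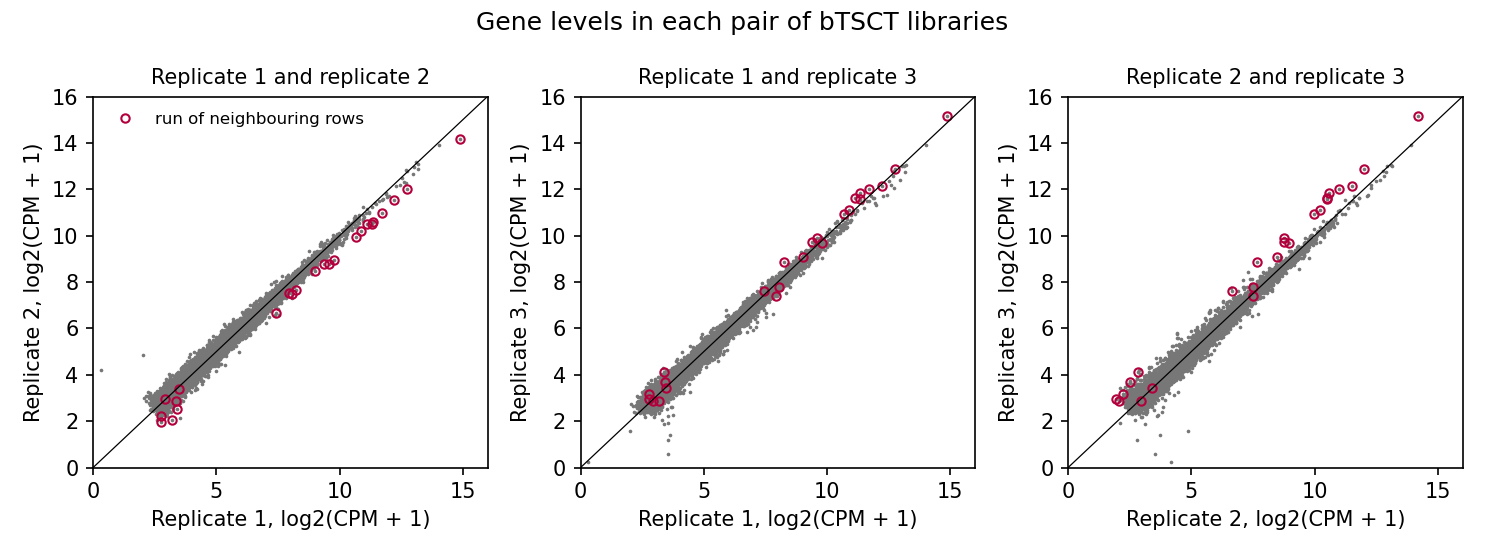
Level of each gene with a mean of 5 CPM or more in the 3 pairs of bTSCT libraries, as log2(CPM + 1) on both axes. Grey points are single genes, red circles are members of the run of 37 neighbouring rows and the line marks equal levels. Most points lie on the line, and most members of the run lie on the replicate 3 side of it in the comparison of replicates 2 and 3.

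Few genes differed between libraries by 1 or more in log2(CPM + 1), a scale on which 1 is a doubling of CPM + 1 and more than a doubling of the level itself. Of 10151 genes with a mean of 5 CPM or more, 57 (0.562%) had a range that wide and 5 had a range of 2 or more. The range was under 0.5 for 91.8% of the genes, with a median of 0.23. Against counting noise alone, 7741 of the 10151 genes (76.3%) differed between the 3 libraries by the chi-square test with Benjamini-Hochberg adjustment. Simulated libraries with the fitted spread gave 7962 such calls among the unchanged of 10137 genes, so this count does not point to differences of particular genes. Against the spread shared by genes of similar level, a negative binomial deviance test at edgeR's trended dispersion called 88. All 57 wide-range genes passed the first test and 43 passed the second. The genes were picked by their range in the same counts, which made passing the first test close to certain. Neither result is therefore separate support. The run of abundant rows contributed 11 of the 57, out of 24 members tested, and 46 came from the 10127 other genes.

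The wide-range genes departed most often in replicates 2 and 3. The library farthest from the median was replicate 3 for 29 genes, of which 15 were higher and 14 lower there. It was replicate 2 for 24 genes, of which 5 were higher and 19 lower, and replicate 1 for 4 genes, all of them higher. Without the run these totals were 27, 15 and 4. All 15 genes higher in replicate 3, and nearly all of the 19 lower in replicate 2, had the order replicate 3, then 1, then 2. That order was found both inside and outside the run. Among all genes outside the run with a mean of 5 CPM or more, 15.6% had it. The departures in replicates 2 and 3 thus largely share 1 order of the libraries and may not be separate ones. Without replicate 3 the number of genes with a range of 1 or more between the remaining libraries was 5, without replicate 2 it was 16 and without replicate 1 it was 48. For the same CPM values, a range over a pair of libraries cannot exceed that over all 3, and equals it only where the pair holds both extremes.

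The 5 genes with a range of 2 or more had mean levels between 5.88 and 10.9 CPM. ENSBTAG00000065013 had 17.2 CPM in replicate 2 (691 counts) against 0.25 CPM in replicate 1 (8 counts) and 0.199 CPM in replicate 3 (7 counts), a ratio of 76.7 to the mean of the other libraries. ENSBTAG00000068105 was also highest in replicate 2, with 27.8 CPM against 3.06 CPM in replicate 1 and 1.96 CPM in replicate 3, a ratio of 11.1. ENSBTAG00000008953 was lowest in replicate 3, with 0.483 CPM (17 counts) against 10.7 CPM in replicate 1 and 10.5 CPM in replicate 2. ENSBTAG00000031231 likewise had 1.62 CPM in replicate 3 against 11.4 CPM in replicate 1 and 12.4 CPM in replicate 2. Each of these is a difference between single libraries, with no second library to measure the error of the one that departs.

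**Figure D3:**
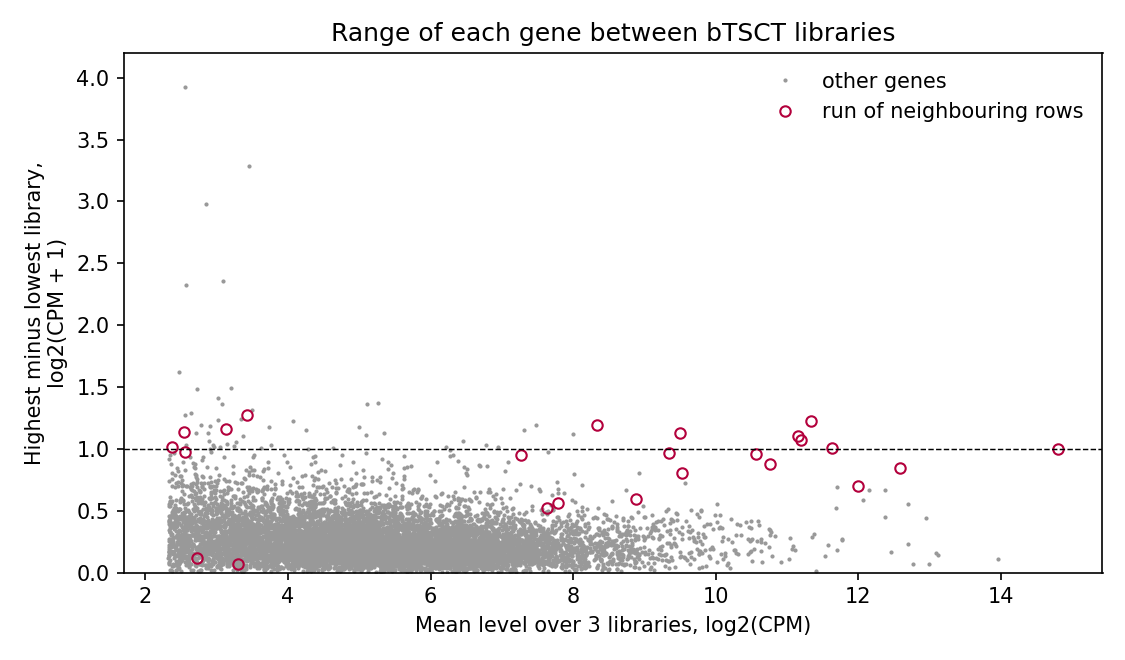
Range between the highest and lowest of the 3 libraries in log2(CPM + 1) (y axis) against the mean level in log2(CPM) (x axis) for 10151 genes. Grey points are single genes, red circles are members of the run of 37 neighbouring rows and the dashed line marks a range of 1. The line is reached by 57 genes, 11 of them in the run.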

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

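Library agreement, genes detected, top 10 and top 100 shares and both counts of differing genes were recomputed under the alternatives that apply to each. Of 65 values, 48 stayed within the spread between libraries or within 1.5 times the count reported. Some of the 48 could not do otherwise: scaling and pseudocount cannot change rho, and leaving out 1 library cannot move top shares that far. Without 1 library, agreement is that of 1 pair, judged against the spread of the pairs themselves. DESeq2 size factors and plain totals kept r, the biological coefficient of variation, detected genes and counts of differing genes within their limits. The level bands, run and row-order values were not recomputed. The number of genes at 1 CPM or more in all 3 libraries stayed between 9898, at a threshold of 5 CPM, and 13186, at 0.5 CPM. It was 12067 after each library was thinned to 10000000 counts, against 12254 at full depth, so this loss of depth lowered it only slightly. Whether greater depth would raise it was not tested. Mean Pearson's r was 0.996 with a pseudocount of 0.1 and 0.993 over genes at 1 CPM or more in at least 1 library, where mean Spearman's rho was 0.993. The 50 most abundant genes took 21.2% of counts. With the run of rows left out of ranking and total, the top 10 remaining genes took 8.57% and the top 100 took 24.2%. The count of 57 wide-range genes depended on its thresholds: it was 21 with a pseudocount of 5, 86 with a mean CPM floor of 1, 20 with a floor of 20 and 5 at a range of 2. The count of 7741 genes beyond counting noise was 88 when the negative binomial deviance replaced the Poisson expectation, which allows the spread that genes of a level share. Leaving out 1 library at a time gave a Pearson r from 0.997 to 0.998, a rho from 0.956 to 0.958, a biological coefficient of variation from 11.5 to 13.4%, 12348 to 12395 detected genes, and top 10 and top 100 shares of 10.1 to 11% and 26.7 to 28.0%. It also gave 5 (without replicate 3) to 48 (without replicate 1) wide-range genes, with 16 without replicate 2, and 5463 to 5665 genes beyond counting noise. The planned marker list levels, lineage differences, per-kilobase values and share without mitochondrial genes were not run, because the identifiers could not be paired with symbols or lengths. No paired analysis was possible because all libraries belong to 1 group.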

Other observations

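The tests of the order of rows by chance, of shared reads between adjacent genes, and of the dominant gene of the run were chosen after the result was seen.

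Neighbouring rows of the table deviated together between libraries. Over the 10151 genes with a mean of 5 CPM or more, taken in the order of the table, the log2 ratio of a pair of libraries correlated between adjacent genes with r = 0.112 for replicates 1 and 2, 0.0678 for replicates 1 and 3 and 0.0945 for replicates 2 and 3, a mean of 0.0914. None of 1000 shuffled row orders (0) gave a mean as large, the highest being 0.0262. The mean was 0.0767 without the run of abundant rows and 0.0906 after the median of 20 level bins was removed, which argues against either as the whole cause. At 10 rows apart it was 0.0466 (highest shuffled 0.0258), which argues against reads shared by adjacent overlapping genes as the whole cause but leaves them open as part of it. At 50 rows apart it was 0.0253, only just under the highest shuffled value at 10 rows, so a lack of correlation at that distance is not shown. At 100 rows apart it was 0.00275. What the order of rows stands for is not stated in the table, a shared GC content of neighbours was not tested because no sequence was used here, and no biological explanation was tested.

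In 101 windows of 100 such genes, the median log2 ratio between a pair of libraries exceeded the highest value of 1000 shuffles, 0.11, in 8 windows. The largest was -0.16 on the log2 scale for replicate 1 against replicate 3 in window 62, a difference of -10.4%. In windows 61 and 62, which adjoin, replicate 1 was lower than both other libraries by more than any shuffle gave, at -0.15 and -0.15 in the first and -0.12 and -0.16 in the second. In no window did replicate 2 or replicate 3 depart from both other libraries in this way. Windows 60 and 63, which adjoin these on either side, were also among the 8, each by 1 pair. The values were -0.13 for replicate 2 against replicate 3 in window 60 and -0.15 for replicate 1 against replicate 3 in window 63. Replicate 3 was the highest library in both, so the whole stretch was not particular to replicate 1. Both comparisons of replicate 1 share its chance deviations.

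The 57 genes with a range of 1 or more exceeded what the spread common to genes of their level gives, since 100 negative binomial simulations at the trended dispersion gave 6.06 on average and at most 12. The simulations gave each gene the dispersion of its level and drew genes independently. Genes with a wider spread of their own, or genes that vary together, would therefore also give an excess. It also stays open whether single cultures, separate lines or library preparation differ, because the labels do not say what the replicate numbers stand for.

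The larger share of the run in replicate 3 than in replicate 2 was not due to its most abundant gene alone. Without that gene the ratio of the shares was 1.89, against 1.94 with it. Whether the difference exceeds the ordinary spread of such shares between libraries was not tested. A difference in RNA quality, selection or cell state between the libraries stays open and was not tested, since the members of the run could not be named. For the same reason it could not be checked whether the run holds mitochondrial, ribosomal protein or histone genes, whose shares were not computed.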
